A study of Mus musculus with 8 samples.

How the data were processed

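The data were 4 peak lists from chromatin immunoprecipitation with sequencing (ChIP-seq), 1 for each of 2 GATA1fl and 2 GATA1s libraries made from G1ME cells 42 h after transduction. The labels also name 4 input libraries, whose values were not used here. Per the labels' protocols, DNA bound to the HA-tagged proteins was isolated with an anti-HA antibody from sonicated nuclei, and libraries were selected for size on beads before amplification and sequenced on an Illumina instrument. Per the submitters' processing notes, bcl2fastq 1.8.4 and Bowtie 1.0.0 were used and the genome build was mm9. The peak caller, its settings, read filters and the part the inputs played in peak calling are not given in the sources used here. The deposited names of the lists refer to MACS and to a version without blacklisted regions. Peaks were called per library, not on pooled replicates.

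Each list gave a position and 3 values per peak. The fold enrichment is a ratio that the authors deposited, with no stated normalization. The second value is −log10 of the peak's p-value as deposited, and its smallest value of 5 in each list sets the authors' threshold. The third column was read as a false discovery rate, a q-value given as a fraction in the deposited lists, because its values lie between 0 and 1 and fall as the −log10 p-value rises. These values belong to single peaks and were used only to describe, rank or select peaks within a list. No read counts were used, so depth is unknown and the limit of detection of each library cannot be given. A list from a deeper or cleaner library can hold more peaks at one p-value threshold, which changes every count of regions present in one list and missing in another.

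Samples were grouped by the GEO titles. Overlap of lists was counted for peaks sharing at least 1 bp. As background, the peaks of each list were moved along their chromosomes by a random circular shift, 100 times. Merged regions were made with bedtools 2.31.1 from all peaks that overlap by at least 1 bp, and a region counted as called in a list if it held a peak of that list. A GATA1fl-only region was called in both GATA1fl lists and in neither GATA1s list, and GATA1s-only regions the other way round. The same counts were made for the other 2 ways of pairing the 4 lists. Ratios of geometric means carry 95% Poisson intervals on the log scale, and shares carry 95% Wilson intervals. Where a count was 0, a limit of 3 counts was used. Strength was the rank of a region's best −log10 p-value in its list. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The functions were tested on 18100 simulated regions with known membership, where all 9 checked counts were found exactly. A planted difference of 10 percentage points between 2 classes came out as 8.30, and 6 of 200 simulations without a difference gave a p under 0.05. Simulated regions were drawn independently of each other, so this does not cover regions that lie in clusters.

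The definitions of overlap and of the region classes, the rule for named regions, and the alternatives for the overlap of lists and for the GATA1fl-only and GATA1s-only regions were fixed before the data were examined, apart from those said to be added. The rule named the 5 regions with the best mean percentile rank in their own lists, for GATA1fl-only, GATA1s-only and all 4 lists. The counts of strong regions absent from the other form, the tests of neighbouring regions and of chromosomes, and the alternatives at a false discovery rate of 0.05 and at 2491 peaks per list were added later. Every alternative for the number of regions in all lists, for percentile ranks, for strong absent regions and for neighbouring regions was also added later. Among these was a paired t interval for the neighbour shares over the 2 replicate numbers. The alternatives fixed beforehand held each list to the length of the shortest (14328 peaks), kept the stronger 50% of each list, required a reciprocal overlap of 50%, removed the widest 5% of regions, and left out each replicate.

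Replicate numbers are shared by the 2 forms. In sum, lists with the same number shared more regions than crossed lists at equal lengths, but with all peaks the sums were 2530 and 2556. At equal lengths the pairs of the same number gave 751 and 956 regions and the crossed pairs 743 and 395. GATA1fl replicate 1 thus shared about as many with either GATA1s list. The labels do not say what a number marks. Comparisons of erythroid, megakaryocytic and other gene lists, of promoter and intron locations, and of GATA motifs had also been planned. They need an mm9 annotation or sequence. The gene table at hand was on GRCm38.p6, coordinates were not converted between builds, and these comparisons were not run.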

Results

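The series mapped where 2 forms of the transcription factor GATA1 bound the genome of G1ME cells, an immortalised mouse progenitor line that lacks GATA1, is arrested before it commits to the erythroid or the megakaryocytic lineage, and can resume development along either once GATA1 is supplied. GATA1fl is the full-length protein, a zinc-finger factor that activates and represses genes of red cells and megakaryocytes. GATA1s is a shorter form without the N-terminal domain and is the form made by the GATA1 mutations of Down syndrome-associated leukaemia. Each form carried an HA tag, was delivered by retrovirus, and was precipitated with an antibody against the tag 42 h after transduction. There were 2 ChIP libraries for each form, and 1 input library was matched to each of the 4. The comparison asked whether the N-terminal domain changes which sites GATA1 occupies in these cells at 42 h. No values used here show whether the cells were still bipotential then, or equally so with both forms. The values are the peaks that the authors called in each ChIP library. Read depth is unknown from these lists, and no values of the input libraries were analysed here. Nothing in the labels says that the replicates came from separate cultures, so their spread may be technical.

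GATA1fl replicate 1 held 24579 peaks, GATA1fl replicate 2 held 14328, GATA1s replicate 1 held 26024 and GATA1s replicate 2 held 28420. Both GATA1s lists were longer than both GATA1fl lists, but the 2 GATA1fl lists differed more from each other than GATA1fl replicate 1 differed from either GATA1s list. The median peak was 595 bp wide in GATA1fl replicate 1, 618 bp in GATA1fl replicate 2, 615 bp in GATA1s replicate 1 and 687 bp in GATA1s replicate 2. The lists covered 15.7, 9.44, 17.1 and 20.8 Mb of the genome in the same order. The median fold enrichment given by the authors was 12.9, 11.4, 10.7 and 10.1, and the smallest −log10 p-value was 5 in each list. The lists differed in how many calls were secure by the authors' own false discovery rate. A rate of 0.05 or lower was given to 42.3% of the peaks of GATA1fl replicate 1 (95% Wilson interval 41.6 to 42.9), 17.4% of GATA1fl replicate 2 (16.8 to 18.0), 22.5% of GATA1s replicate 1 (22.0 to 23.1) and 45.0% of GATA1s replicate 2 (44.4 to 45.5). In GATA1fl replicate 2, 3515 peaks had a rate of 1. Each such interval covers counting error only.

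Peaks of the 2 forms overlapped far more often than shifted peaks did. The share of overlapping peaks depended on the lengths of both lists. Of the peaks of GATA1fl replicate 2, the shortest list, 65.1% (Wilson interval 64.3 to 65.8) overlapped a peak of GATA1fl replicate 1, 65.4% (64.6 to 66.2) overlapped one of GATA1s replicate 2, and 59.6% (58.8 to 60.4) overlapped one of GATA1s replicate 1. Peaks of GATA1fl replicate 1 overlapped the other GATA1fl list in 38.1% of cases, GATA1s replicate 1 in 47.8% and GATA1s replicate 2 in 51.4%. Peaks of GATA1s replicate 1 overlapped GATA1s replicate 2 in 53.4% of cases, GATA1fl replicate 1 in 45.1% and GATA1fl replicate 2 in 33.0%. After circular shifts of the peaks along their chromosomes, the highest overlap of any pair in 100 shifts was 1.99%. The Jaccard index, the shared bases as a share of all bases covered by either list, was 29.7% for the 2 GATA1fl lists and 31.1% for the 2 GATA1s lists. The 4 comparisons between forms gave 26.6% ± 1.63 (SD over the 4 pairs, which share lists), from 25.1 to 28.1%. Both values within a form lay above the 4 values between forms. The 4 lists can be split into pairs in only 3 ways, so no exact test over the lists can give a p below 0.33.

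**Figure D1:**
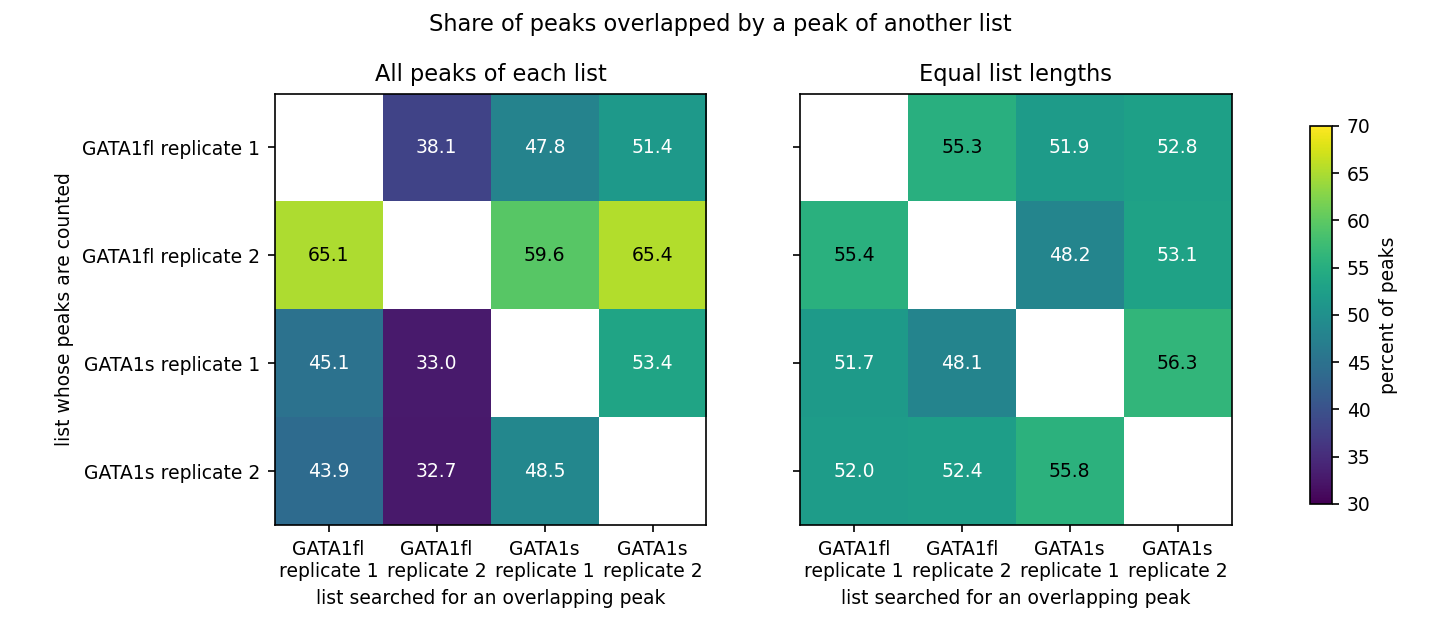
Percent of the peaks of each list (rows) that overlap a peak of another list (columns) by at least 1 bp, for all peaks (left) and with every list held to its 14328 strongest peaks (right); the colour gives the same percent as the number in the cell. At equal lengths, overlap within a form was 55.3 to 56.3% and overlap between forms 48.1 to 53.1%.

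With every list held to the 14328 strongest peaks, both the share of overlapping peaks and the Jaccard index were higher within forms than between them. GATA1fl replicate 1 and GATA1fl replicate 2 then shared a Jaccard index of 34.5%, the GATA1s lists shared 34.3%, and the pairs of different forms shared 29.0 to 31.6%. Among peaks at a false discovery rate of 0.05 or lower, where the lists hold between 2491 and 12775 peaks, the index within forms fell below that between forms, by a mean difference of -1.19 percentage points against 3.85 for all peaks. That threshold was added after the data were examined.

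Peaks of the 4 lists merged into 52636 regions, of which 6540, or 12.4%, were called in all 4 lists. Regions called in both GATA1fl lists were mostly also GATA1s regions. Of 9148 such regions, 71.5% (Wilson interval 70.6 to 72.4) were called in both GATA1s lists, 18.0% in 1 of them and 10.5% (9.87 to 11.1) in neither. Of 13621 regions called in both GATA1s lists, 48.0% were called in both GATA1fl lists, 25.3% in 1 and 26.7% (26.0 to 27.5) in neither. There were thus 959 GATA1fl-only regions, called in both GATA1fl lists and in neither GATA1s list, and 3638 GATA1s-only regions. At equal list lengths these shares were nearly the same for both forms. Of the regions in both GATA1fl lists 63.6% were then in both GATA1s lists and 16.3% in neither, and the reverse shares were 62.3% and 17.5%. The counts were 1269 and 1388, so the ratio of GATA1s-only to GATA1fl-only regions went from 3.79 to 1.09 once the lists had the same length. Equal lengths bring these shares together and push this ratio towards 1 by construction.

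With all peaks and at equal lengths, more regions separated the lists by GATA1 form than in either other way. Splitting the lists by replicate number gave 1676 regions called only in the 2 lists numbered 1 and 854 called only in the 2 lists numbered 2. The remaining split gave 2129 regions for GATA1fl replicate 1 with GATA1s replicate 2 and 427 for GATA1fl replicate 2 with GATA1s replicate 1. Because each list enters a split once, the geometric mean of its 2 counts is less affected by list length. It was 1868 for the split by form, 1196 for the split by replicate number and 953 for the crossed split. The split by form exceeded the split by replicate number 1.56-fold (95% counting interval 1.48 to 1.65) with all peaks and 1.57-fold (1.47 to 1.66) at equal lengths. The split by replicate number in turn exceeded the crossed split 1.25-fold (1.17 to 1.34) and 1.56-fold (1.45 to 1.69). At equal lengths GATA1fl replicate 1 alone with GATA1s replicate 1 called 751 regions and with GATA1s replicate 2 called 743. GATA1fl replicate 2 called 956 with GATA1s replicate 2 and 395 with GATA1s replicate 1, which set most of that gap. The order of the splits by replicate number and crossed depended on list length. Their sums were 1707 and 1138 regions at equal lengths, but 2530 and 2556 with all peaks, and the Jaccard index with all peaks was 27.8 and 25.2% for lists of the same number and 28.1 and 25.1% for crossed lists. These intervals treat regions as independent counts and say nothing of the spread between further libraries.

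**Figure D2:**
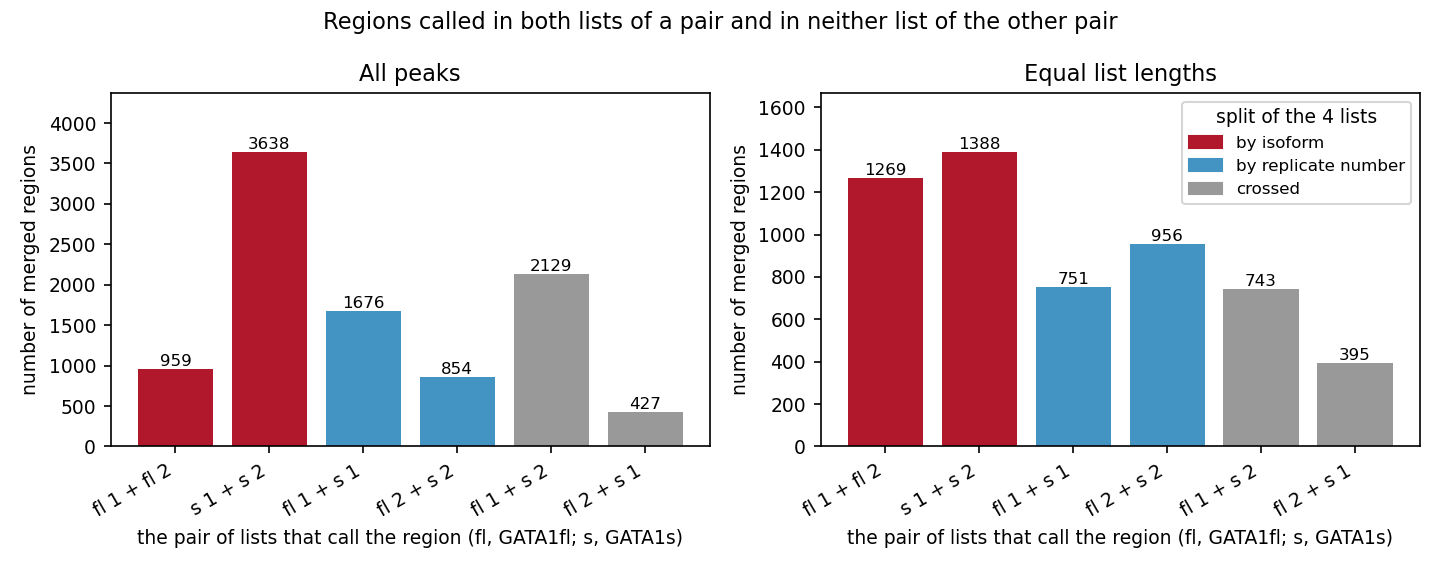
Number of merged regions (vertical axes, from 0) called in both lists of a pair and in neither of the other 2, for the 3 ways of splitting the 4 lists into pairs, with all peaks (left) and with 14328 peaks per list (right). The 2 bars of the split by form are 959 and 3638 on the left and 1269 and 1388 on the right, where they are the 2 highest.

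Counts of both classes rose whichever list was left out. A form with 1 list no longer needs a second call, and the other form has fewer lists to be absent from. GATA1s-only regions stayed the more numerous except without GATA1fl replicate 2, the shortest list. Without GATA1fl replicate 1 there were 3862 GATA1fl-only and 6294 GATA1s-only regions, and without GATA1fl replicate 2 there were 9542 and 4452. Leaving out GATA1s replicate 1 gave 1614 and 14252, and leaving out GATA1s replicate 2 gave 1981 and 13034. Within the single pair of replicates numbered 1, whose lists are of similar length, 12646 regions were called with GATA1fl and not GATA1s and 14184 the other way. Within the pair numbered 2 the counts were 4919 and 18970.

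Few of the strongest regions of either form lacked a call with the other form. Of the 1314 regions among the 2000 strongest of both GATA1fl lists, 0 lacked a call in both GATA1s lists, which allows a share of up to 0.228%. Of the 1354 regions among the 2000 strongest of both GATA1s lists, 1 lacked a call in both GATA1fl lists. At equal list lengths the counts were 4 of 1314 (0.304%) and 1 of 1354. The split by replicate number gave 2 of 1228 regions for the lists numbered 2 and 0 of 1226 for those numbered 1, with all peaks. Among the 5000 strongest the numbers were 41 of 3290 GATA1fl regions (1.25%, Wilson interval 0.920 to 1.69) and 41 of 3153 GATA1s regions (1.30%, 0.960 to 1.76). The split by replicate number gave 14 of 2937 and 17 of 3093 at that depth of ranking, and the crossed split gave 1 of 2681 and 0 of 3006. At equal list lengths the GATA1fl count among the 5000 strongest rose to 124 of 3289 and the GATA1s count to 65 of 3152. The split by replicate number then gave 32 of 2937 for the lists numbered 1 and 51 of 3093 for those numbered 2, and the crossed split 7 of 2681 and 5 of 3005. The interval of the GATA1s share (2.06%, 1.62 to 2.62) overlapped that of the lists numbered 2 (1.65%, 1.26 to 2.16).

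**Figure D3:**
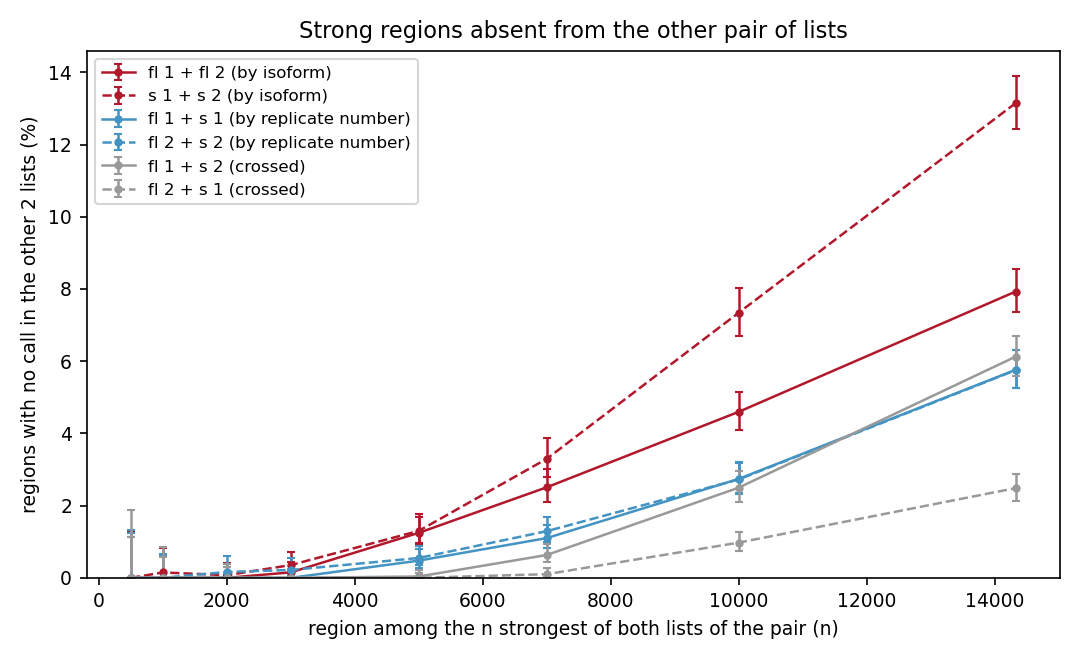
Percent of regions with no call in the other 2 lists (vertical axis, from 0) among regions that rank within the n strongest of both lists of a pair (horizontal axis), for all 6 pairs of lists; bars are 95% Wilson intervals. Among the 3000 strongest, 3 of 1980 GATA1fl regions and 7 of 1980 GATA1s regions were absent, and the 2 curves of the split by form lie above the others from 5000 on.

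GATA1fl-only and GATA1s-only regions were of intermediate or low strength within their own lists. On a percentile scale where the strongest peak of a list is near 100, GATA1fl-only regions had a median of 52.6 in GATA1fl replicate 1 and 35.9 in GATA1fl replicate 2. GATA1s-only regions had medians of 47.2 and 46.1 in the GATA1s lists. Regions called in all 4 lists had medians between 74.4 and 85.9, and regions called in a single list had medians between 22.8 and 30.9. A rank between these may follow from being called in 2 lists, whatever the form. Regions called in 2 lists under the other splits were not ranked, so the ranks are not shown to be particular to either class. The median width was 701 bp for GATA1fl-only, 774 bp for GATA1s-only and 971 bp for regions in all 4 lists.

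Coordinates below are on mm9, counted from 1, and the genes and annotations at these positions were not assigned here, because no mm9 annotation was used. The −log10 p-value of 310 recurred at the top of the lists, in 1, 2, 2 and 15 peaks in the order GATA1fl replicates 1 and 2 and GATA1s replicates 1 and 2, so the order among the top regions is not resolved. Among the 5 regions of best mean rank called in all 4 lists, 1 lay on chromosome 9 from 89853759 to 89856769, with a −log10 p-value of 310 in each list and an authors' fold enrichment of 25 and 27.9 in the GATA1fl lists and 35.5 and 63.7 in the GATA1s lists. Another lay on chromosome 7 from 86149039 to 86151642, with fold enrichments of 53.3, 68.3, 66.5 and 96.8 in that order of lists, and another on chromosome 11 from 104829023 to 104830406, with 93.8, 98.4, 196.4 and 107.8. The 2 others were on chromosome 4 from 138727980 to 138729582 (58.3, 52.4, 79.3 and 49.3) and on chromosome 18 from 78327472 to 78328933 (92.7, 119.1, 88.7 and 120.6). Fold enrichments are each list's own values and are not compared between lists.

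The strongest GATA1fl-only region lay on chromosome 2 from 33112257 to 33113163, with a fold enrichment of 28.2 in replicate 1 and 14.1 in replicate 2, at a mean percentile of 88.3. A region on chromosome 9 from 77605035 to 77605755 had 30.7 and 26.6, and one on chromosome 10 from 13221907 to 13222773 had 17.2 and 19.9. The 2 that followed were on chromosome 13 from 47206429 to 47207019 (29.4 and 22.8) and on chromosome 11 from 95638544 to 95639690 (11.1 and 15.2). The strongest GATA1s-only region lay on chromosome 14 from 120964324 to 120965472, with a fold enrichment of 20.6 in GATA1s replicate 1 and 16.8 in replicate 2, at a mean percentile of 97.0. It was followed by regions on chromosome 5 from 125826706 to 125828045 (25.8 and 19.5), on chromosome 10 from 128763166 to 128763839 (18.3 and 21.1), on chromosome 13 from 42879442 to 42880746 (16.4 and 24.6) and on chromosome 4 from 130451884 to 130453067 (17.5 and 10.3). By the definition of their classes, none of these 10 regions overlapped a call of the other form in either replicate. A missing call does not show that binding was absent, since a peak under the authors' threshold is not listed.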

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

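By geometric mean the split by form was the highest in each setting tried with all 4 lists. The split by form over the highest other split was 1.56-fold with all peaks, 1.53-fold to 1.64-fold in the 4 alternatives fixed beforehand, 1.67-fold with the 2491 strongest peaks of each list and 2.04-fold at a false discovery rate of 0.05 or lower, where the crossed split gave no ratio. At that rate it held 0 regions on one side and 1968 on the other, the most of any pair there, against 73 and 848 by form and 329 and 45 by replicate number. A reciprocal overlap of 50% moved no count by over 1.5 times, with the largest change from 41 to 57 strong GATA1s regions absent from GATA1fl (51 for GATA1fl). The difference in Jaccard index within minus between forms reversed to -1.19 percentage points at a false discovery rate of 0.05, where list lengths differ most; leaving out 1 replicate gave 3.10 to 5.91. Counts of GATA1fl-only regions moved from 959 to 520 with the stronger 50% of each list, 265 with 2491 peaks per list and 73 at a false discovery rate of 0.05, and to between 1614 and 9542 with 1 replicate left out. GATA1s-only regions moved from 3638 to 1388 at equal list lengths, 1749 with the stronger 50%, 247 with 2491 peaks per list and 848 at that false discovery rate, and to between 4452 and 14252 with 1 replicate left out. Fewer peaks, or fewer lists to satisfy, change these counts by construction. Regions called in every list fell from 6540 to 3999 with the stronger 50% and 2014 at the false discovery rate, and were 7201 to 9180 with 1 replicate left out. The mean percentile of GATA1fl-only regions had a median of 42.5, with 25.4 to 47.7 when 1 replicate was left out. That of GATA1s-only regions was 45.5, and became 41.2 at equal lengths, 42.8 with the stronger 50%, 44.3 without the widest 5% of regions and 42.5 at the false discovery rate, with 33.1 to 50.2 when 1 replicate was left out. Of the 5000 strongest, the 41 GATA1fl regions absent from GATA1s became 124 at equal lengths, 139 with the stronger 50% and 80 without the widest regions, and 126 to 274 with 1 replicate left out. The 41 GATA1s regions absent from GATA1fl became 65, 147 and 82 in the same settings, 306 at the false discovery rate, and 110 to 556 with 1 replicate left out. Removing the widest regions removes strong ones, so that weaker regions enter the 5000. The share near regions called in all lists, GATA1fl-only minus GATA1s-only, was 10.7 percentage points and 0.155 to 14.8 with 1 replicate left out, lowest without GATA1fl replicate 1. With the replicate number as a block (replicate block, calls of 1 form alone within each same-numbered pair) it was 5.39 points (95% paired t interval over 2 pairs -30.8 to 41.5). Counts of GATA1fl-only and GATA1s-only regions already require the difference in both pairs. Alternatives for regions in every list, percentiles, strong absent regions and neighbours were all added after the data were examined. The alternatives for gene lists, genomic location and motifs were not run. Depth is unknown and limits what a missing call means.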

Other observations

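The tests of neighbouring regions, of chromosomes and at a false discovery rate of 0.05 or 2491 peaks per list were chosen after the counts had been seen, as was the listing of region clusters; counts at equal list lengths and for the other pairings were fixed beforehand, and were set against explanations afterwards. Regions called in all 4 lists were unevenly spread. Between the outermost peaks of a chromosome, the autosomes held a median of 2.74 such regions per Mb, from 1.68 on chromosome 14 to 4.46 on chromosome 11, and chromosome X held 0.306. When regions with gaps of at most 10 kb were joined, 29 clusters held at least 5 regions called in all 4 lists. The highest number was 9, reached on chromosome 9 from 65366949 to 65429318, on chromosome 6 from 31513715 to 31576012 and on chromosome 7 from 71136069 to 71205361. A cluster of 24 regions on chromosome 8 from 124798765 to 124874312 held 8 called in all 4 lists, 1 GATA1fl-only region and 0 GATA1s-only regions.

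At least 2 GATA1fl-only regions lay in 41 clusters and at least 2 GATA1s-only regions in 186, while 88 clusters held both kinds; whether regions of 1 form gather was not tested. The most GATA1fl-only regions in a cluster were 3, on chromosome 18 from 64692931 to 64703744, beside 1 region in all 4 lists and 0 GATA1s-only regions. The most GATA1s-only regions were 4, reached on chromosome 8 from 122789547 to 122822443 and from 119539491 to 119670050 and on chromosome 16 from 91338058 to 91392935, each with 0 GATA1fl-only regions. GATA1fl-only and GATA1s-only regions were spread differently over the 20 chromosomes (chi-square 59.0 over chromosomes other than Y, two-sided permutation of the class over regions, 100000 draws, p = 2e-05), and at equal list lengths the permutation p was 0.0052. The same permutation test gave p = 0.39 for the split by replicate number and 0.38 for the crossed split, and 0.24 and 0.74 at equal lengths. Those splits held 2530 and 2556 regions against 4597 by form, and 1707 and 1138 against 2657 at equal lengths. With fewer regions these tests could miss a spread as uneven, so the p-values do not rank the splits. All tests of chromosomes and neighbours that permute or count regions treat them as independent and do not cover the spread between 2 libraries per form. Chromosome 19 held 4.80% of GATA1fl-only and 2.39% of GATA1s-only regions (Fisher's exact test adjusted over 20 chromosomes, p = 0.0040), and chromosome 11 held 9.18% and 6.40% (adjusted p = 0.035). At equal list lengths 0 chromosomes passed the adjusted test and 2 had an unadjusted p under 0.05. Chromosome 7 came nearest there, with 8.04% of GATA1fl-only and 5.12% of GATA1s-only regions (Fisher's exact test, unadjusted p = 0.0027, adjusted p = 0.054). Peaks on chromosome Y appeared only in the lists numbered 2, with 6 in GATA1fl replicate 2 and 8 in GATA1s replicate 2.

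GATA1fl-only regions lay beside commonly bound sites more often than GATA1s-only regions did. Within 10 kb of a region called in all 4 lists lay 23.0% of GATA1fl-only regions (221 of 959, Wilson interval 20.5 to 25.8) and 12.4% of GATA1s-only regions (450 of 3638, 11.3 to 13.5), a difference of 10.7 percentage points (two-sided permutation of the class over regions, p = 1e-05, the smallest that 100000 draws can give); at equal list lengths it was 8.11 points. The other 2 splits differed less, with 20.7% against 16.6% by replicate number and 18.7% against 15.5% when crossed, and in both the higher share was on the side of GATA1fl replicate 1. Regions called in a single list gave 18.6% for GATA1fl replicate 1, 13.4% for GATA1fl replicate 2, 10.2% for GATA1s replicate 1 and 12.3% for GATA1s replicate 2. At equal lengths GATA1fl and GATA1s gave 15.5% and 8.56% in the lists numbered 1 and 11.5% and 11.1% in those numbered 2. The tables argue against percentile rank within a region's own lists as the whole cause, with 10.8 points within 5 bins of that rank. An equal rank is not an equal strength in lists of different length, so strength itself was not matched between the forms. The values also argue against the spread over chromosomes as the whole cause, with 10.3 points within chromosomes. They argue likewise against single sites split into 2 calls as the whole cause, with 7.79 points for gaps of 1 kb to 10 kb. Shorter gaps were left out there, so split sites stay open as a part of the 10.7 points. GATA1fl replicate 1 alone stays open as a source. The replicates numbered 2 differed by 2.96 points within the same bins and those numbered 1 by 8.30. Over the 2 same-numbered pairs the mean difference without bins was 5.39 points (95% paired t interval -30.8 to 41.5), and without GATA1fl replicate 1 the difference between the classes was 0.155 points. The 2.96 points exceed the range of permuted differences (-1.12 to 1.13), the bound set before this later-added test was run, but that range covers regions and not libraries. They lie below the 5.12 points between the single-list shares of the 2 GATA1fl libraries and above the 2.11 points between those of the 2 GATA1s libraries. Those gaps were taken without bins and over regions called in a single list, an unlike set, so they are only a rough guide. The comparison of 1 library with 1 thus does not decide. Library background, the amount of each protein and a difference between the forms were not tested and stay open.

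The larger number of GATA1s-only than GATA1fl-only regions, 3.79-fold with all peaks, may come from the lengths of the lists, but the tests cannot decide it. At equal list lengths the ratio was 1.09, and equal lengths push it towards 1 by construction. In the replicates numbered 1, which leave out the short list of GATA1fl replicate 2, regions called with GATA1s alone outnumbered those with GATA1fl alone 1.12-fold, near the ratio of 1.06 between the lengths of these 2 lists, so this value also decides nothing about the short list. Whether the list is short because of depth, antibody yield or binding cannot be read from peak calls, and a biological difference in the number of GATA1s sites stays untested.

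The excess of regions that separate the lists by form was set against chance failures of weak calls. With 3 possible splits no share under 0.05 exists; 1 of the 3 splits, the split by form, gave a geometric mean as large as 1868, and the highest other was 1196. Failures that strike each list independently predict equal splits if detection depends on strength in the same way in each list. The ratios were 1.57 at equal list lengths (counting interval 1.47 to 1.66) and 1.56 with all peaks (1.48 to 1.65). The lists differed in their share of secure calls, so that condition may not hold. The 2 splits not made by form also differed, 1.56-fold at equal lengths (1.45 to 1.69). The ratios thus cannot decide for or against independent failures. Insecure calls also stay open as the cause. The 2491 strongest peaks of each list, all at a false discovery rate of 0.0496 or lower, gave a ratio of 1.67 (1.45 to 1.93), but a list cut short also lacks regions that only rank lower in it. Held against the full lists, regions among these peaks in both lists of a pair lacked a call in the other 2 lists in 2 and 2 cases by form, 0 and 3 by replicate number and 0 and 0 when crossed, too few to decide. At a rate of 0.05 or lower in both lists, the cases were 12 of 2383 GATA1fl and 246 of 4667 GATA1s regions. They were 41 of 4154 and 5 of 2349 for the lists numbered 1 and 2, and 190 of 6011 and 0 of 2088 when crossed. The GATA1s share (5.27%) was the highest, but the GATA1fl share (0.504%) lay between those of the other pairs. The lists at that rate differ in length, so these larger counts do not decide either. The test of all peaks at a rate of 0.05 or lower was chosen after the counts had been seen, though its bound was set before it was run. The ratio was 2.04 (1.68 to 2.49), above that bound. That bound was wrong there because it ignored the crossed split, with 1968 regions on one side and 0 on the other, and lists of 2491 to 12775 peaks; the Jaccard difference was -1.19 points. Whether libraries resemble each other for reasons other than the form also stays open, since 2 libraries per form cannot separate preparation from form. By geometric mean the split by replicate number exceeded the crossed split 1.25-fold with all peaks and 1.56-fold at equal lengths. With 2491 peaks per list it did so 3.03-fold. Similarity between lists of the same number would not raise the split by form, so these ratios are no sign of preparation effects within it.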
